A study of Mus musculus with 4 samples.

How the data were processed

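RNA from 4 samples of T29, a mouse thymic lymphoma cell line, was measured on Affymetrix GeneChip expression arrays. Per the labels, 2 samples were treated with DMSO, the solvent control, and 2 with MRK003, an inhibitor of gamma-secretase (GSI), at a dose written as 5 mM for 36 h. The unit of the dose is given here as the labels write it and could not be checked. The treatment text of the labels is identical for all 4 samples, so the groups were taken from the sample titles. Total RNA was labelled with biotin in a one-cycle reaction, per the labels' protocols. Nothing in the labels says whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

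The deposited values were expression on the log2 scale, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. Probe-level files were not used here, so neither the background correction nor the normalization could be repeated. Such values compress differences of dim probe sets, and a normalization between arrays assumes that most genes do not shift one way. The table held 45101 probe sets with 0 missing values. The 64 control probe sets were left out of tests. Of the remaining 45037 probe sets, 34945 had 1 gene symbol in the platform annotation used here, 932 had several and 9160 had none. Symbols were updated through the gene identifier to the RefSeq annotation of GRCm38.p6, which held 34741 of the 34945. That annotation was used only for names and for the order of neighbouring genes.

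For each gene, the 1-symbol probe set with the highest mean over the 4 arrays stood for the gene, giving 18193 genes. More than 1 probe set was measured for 9010 of these genes, and in 0 of them did probe sets past the threshold point in both directions. GSI was compared with DMSO with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term, two-sided), and p-values were adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05. The fit had 5.80 total degrees of freedom, of which 3.80 came from the prior. Standard errors (SE) are those of the moderated fit, and SD is given over the 2 arrays of a group. Fold changes are back-transformed log2 differences. No filter on dim probe sets was applied.

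A set of 24 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera in limma with a preset correlation of 0.01 and adjustment over the 24 lists. Camera was repeated with the correlation estimated per list, and fry was run as a further set test, with its directional and its mixed p-value. With an estimated correlation camera rests on the 2 residual degrees of freedom. A list could hardly pass it after adjustment, so a failure there says little against the list. List counts are given over all genes and adjusted over the list alone. List members without a 1-symbol probe set were not analysed here. The genes named were the 15 largest rises and 15 largest falls among called genes whose arrays did not overlap between groups, leaving out unnamed gene models. All measured members of the Notch target list were added, together with up to 4 called members of each other list with the largest changes. A list without a called member contributed the 2 members with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

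The alternatives were every non-control probe set tested on its own, the mean of a gene's probe sets, dim genes left out, eBayes with an intensity trend and robust prior, arrays centred on their medians, cyclic loess, the replicate number as a block, a 2-fold minimum, and each array left out in turn. When an array was left out, the remaining array of its group was assumed to vary like the other group. For lists, camera by ranks was also run. Groups of 2 are too small for a count of other splits of the samples or for an outlier test.

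The scripts were tested on simulated data drawn for the same 18193 genes and 4 arrays. With 200 genes changed, the limma step recovered 100% of changes of 2 on the log2 scale, 85.1% of changes of 1 and 1.49% of changes of 0.5. Recovery after Benjamini-Hochberg depends on how many genes change. More than 200 genes were called in the data, so these shares need not hold there. Of the calls, 4.62% were unchanged genes. All 3 lists shifted by 0.3 were called, and 0 of 16 lists without a shifted member. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. In the count of neighbouring genes, 1 of 50 random call sets had a p under 0.05, and with 40 neighbouring pairs planted 52 were counted. For arrays, the number of samples limits the precision. Here the median SE of a log2 difference was 0.0987, and the smallest called difference was 0.44. Figures were drawn with matplotlib 3.10.9.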

Results

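Gene expression was measured in T29 cells, a mouse line derived from a thymic lymphoma, after treatment with DMSO or with the gamma-secretase inhibitor MRK003 (GSI). Gamma-secretase cleaves membrane proteins, among them the Notch receptors, whose released intracellular part regulates transcription. There were 2 arrays per group and 18193 genes. The median log2 value per array lay between 4.86 and 4.89. The DMSO arrays correlated with each other at 0.9959 and the GSI arrays at 0.9970, and arrays of different groups at 0.9915 to 0.9940, across probe sets, which are not independent replicates. Between the DMSO arrays 87 probe sets lay 2-fold or more apart, between the GSI arrays 14, and between arrays of different groups 371 to 546. The 3' minus 5' signal of the control probe sets lay between 0.018 and 0.068 for Gapdh and between 0.32 and 0.38 for Actb, both on the log2 scale. For the transferrin receptor control it was 1.30 and 1.65 on the DMSO arrays and 1.66 and 1.36 on the GSI arrays.

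The comparison asked which transcripts change when T29 cells are exposed to the inhibitor. With GSI, the chemokine receptor gene Ccr9 rose 13.3-fold, from a log2 value of 6.47 ± 0.14 to 10.20 ± 0.11 (SD, n = 2; limma, adjusted p = 0.000402). Dtx1, a Notch-regulated ubiquitin ligase gene, fell from 9.49 ± 0.16 to 5.96 ± 0.11, an 11.6-fold difference (SD, n = 2; limma, adjusted p = 0.000534). Il2ra, encoding the alpha chain of the interleukin-2 receptor, was 7.33-fold lower, and Hes1, a transcriptional repressor downstream of Notch, was 4.79-fold lower. In all, 466 genes rose and 284 fell at an adjusted p under 0.05. Of these, 111 rose and 66 fell by 2-fold or more. In all 750 the 2 GSI arrays lay on one side of both DMSO arrays. With 2 arrays per group a call at this threshold already requires that.

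Beside Ccr9, the largest rises included its neighbours in the gene order of GRCm38.p6, Slc6a20a, encoding an amino acid transporter (13.2-fold), and Lztfl1 (5.60-fold). Cpa3, encoding a carboxypeptidase typical of mast cells, rose 6.98-fold and the transcription factor gene Maf 5.46-fold. Lgals1, encoding galectin-1, rose 4.03-fold, from 9.89 ± 0.37 to 11.90 ± 0.46 (SD, n = 2), and did not pass with an intensity trend and robust prior (adjusted p = 0.0772). The related membrane protein genes Ms4a6b and Ms4a4b rose 5.29-fold and 3.24-fold. Further rises were 3.62-fold for the kinase gene Mapk10, 3.60-fold for the steroid-synthesis gene Cyp11a1, 3.29-fold for the adhesion gene Cadm1 and 3.21-fold for both the AP-1 gene Jund and Rhbdl3. Several of the genes named here had dimmer probe sets that did not pass when every probe set was tested. Among them were those of Cyp11a1 (0.40 and 0.34), Jund (-0.38) and Rhbdl3 (0.29), as log2 differences. Papss2, which makes the sulphate donor of the cell, rose 3.15-fold. Trav9d-3, a variable segment of the T cell receptor alpha locus, was 3.54-fold higher, but its probe set can bind related segments, so which of them rose is uncertain.

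Among the falls, the interferon-inducible gene Ifi202b was 13.3-fold lower with GSI, at 9.70 ± 0.04 with DMSO and 5.97 ± 0.09 with GSI (SD, n = 2; limma, adjusted p = 0.000371). Its relative Ifi204 was 5.71-fold lower, and since the family holds near-identical copies the share of each is uncertain. Olfm4, encoding olfactomedin 4, fell 9.97-fold, Exoc3l4 7.49-fold and Afdn, encoding the junction protein afadin, 6.57-fold. Lhfp, Spsb4 and Elovl3, which elongates fatty acids, fell 6.45-fold, 6.22-fold and 5.63-fold. Nrarp, a feedback regulator of Notch signalling, fell 5.34-fold. Wdr25, Uaca and Coro2a fell 4.63-fold, 4.40-fold and 4.29-fold. The lower group mean lay below the array medians for Slc6a20a (3.20), Ms4a4b (4.16) and Rhbdl3 (4.67) among the rises and for Ifi204 (3.32), Olfm4 (3.39), Lhfp (3.65) and Elovl3 (4.12) among the falls. The background level of these probe sets was not analysed here, so the sizes and ranks of these folds are uncertain. The same holds for the sizes given below for Notch4 (4.74 with GSI) and Blnk (4.85 with DMSO). It holds too for Kit (4.69), Gbp8 (4.62) and Gbp2b (3.90) with DMSO. Of the uncalled genes given below, it holds for Itgam (3.27), Gata1 (4.35) and Hes5 (4.68) with DMSO and Hey2 (2.44) with GSI.

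**Figure D1:**
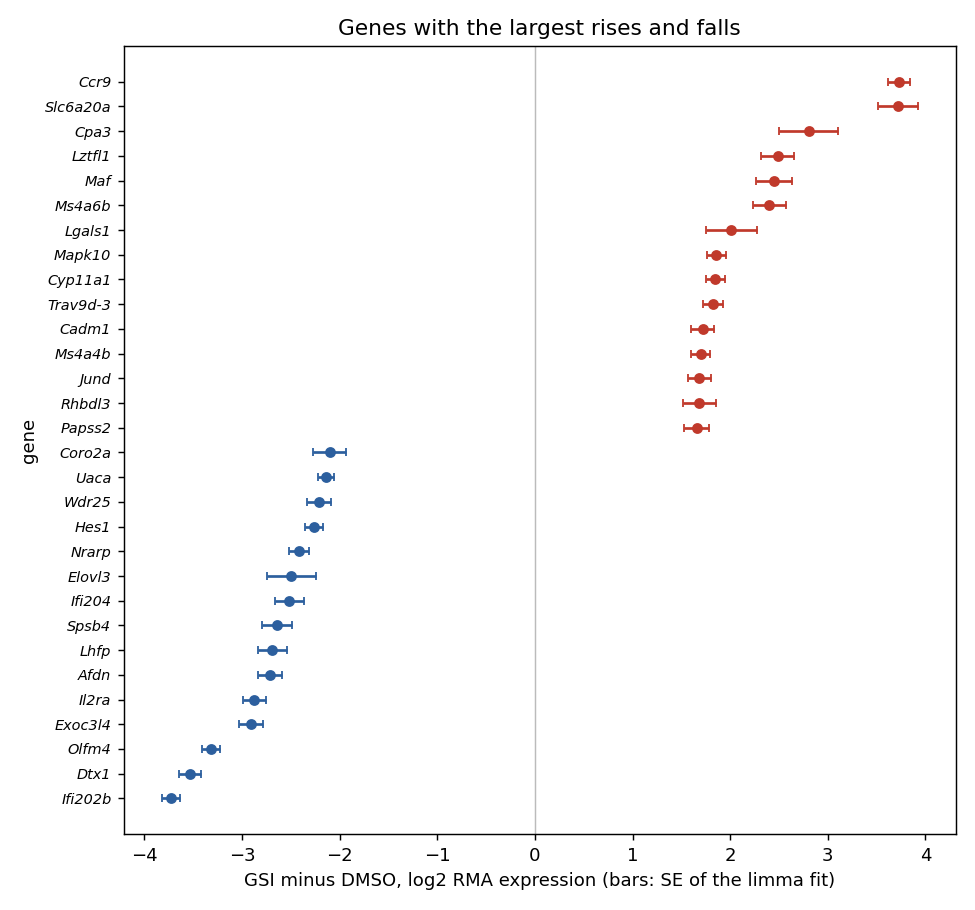
The 15 genes with the largest rises and the 15 with the largest falls, by difference between GSI and DMSO in log2 expression (points, with the SE of the limma fit as bars; 2 arrays per group). Ccr9 lies farthest to the right at 3.73 and Ifi202b farthest to the left at -3.73.

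The counts rested on all 4 arrays: limma called 1 gene up and 5 down without DMSO replicate 1 and likewise without DMSO replicate 2, the same 6 genes (Ccr9, Dtx1, Exoc3l4, Ifi202b, Il2ra and Olfm4), and 0 without GSI replicate 1 or without GSI replicate 2. All 750 genes kept their direction in each of these 4 fits. This had to follow, since their arrays did not overlap between groups, and is no sign of stability. Of the list members named below, Mfng, Notch4, Birc3, Prkcq, Gfi1, Pik3ip1, Cth, Hspd1, Mx1 and Blnk did not pass when every probe set was tested, and Birc3 and Cd247 did not as the mean of their probe sets; others are given with their lists.

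Of 17 measured genes known as Notch targets in T cells, 8 fell, 1 rose and 8 did not pass, and 10 were lower and 1 higher when adjusted over the list alone. The list passed camera downwards (median log2 difference -0.56, adjusted p = 1.73e-06), not with an estimated correlation (adjusted p = 0.466). Its directional fry test had an adjusted p of 0.0114, and it was the only 1 of the 24 lists to pass that test. By the mixed test of fry, which counts changes in either direction, 19 of the 24 lists passed. Besides Dtx1, Il2ra, Nrarp and Hes1, the falls were Ptcra, encoding the pre-T cell receptor alpha chain (3.26-fold), Notch3 (1.99-fold), the growth regulator Myc (1.54-fold) and Notch1 (1.47-fold). The transcription factor gene Gata3 rose 1.55-fold. The members that did not pass were Hey1 (-0.88), Heyl (-0.56), Igf1r (-0.29), Ccnd3 (-0.18), Hey2 (-0.18), Ccnd1 (0.14), Hes5 (0.26) and Il7r (0.37), as log2 differences. Dimmer probe sets of Heyl and Ccnd3, tested among all probe sets, passed at -1.11 and 0.87, and Heyl also passed as the mean of its probe sets (-0.64, adjusted p = 0.0174). In that test of every probe set Myc, Notch1 and Gata3 did not pass (adjusted p = 0.0719, 0.0694 and 0.0733).

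**Figure D2:**
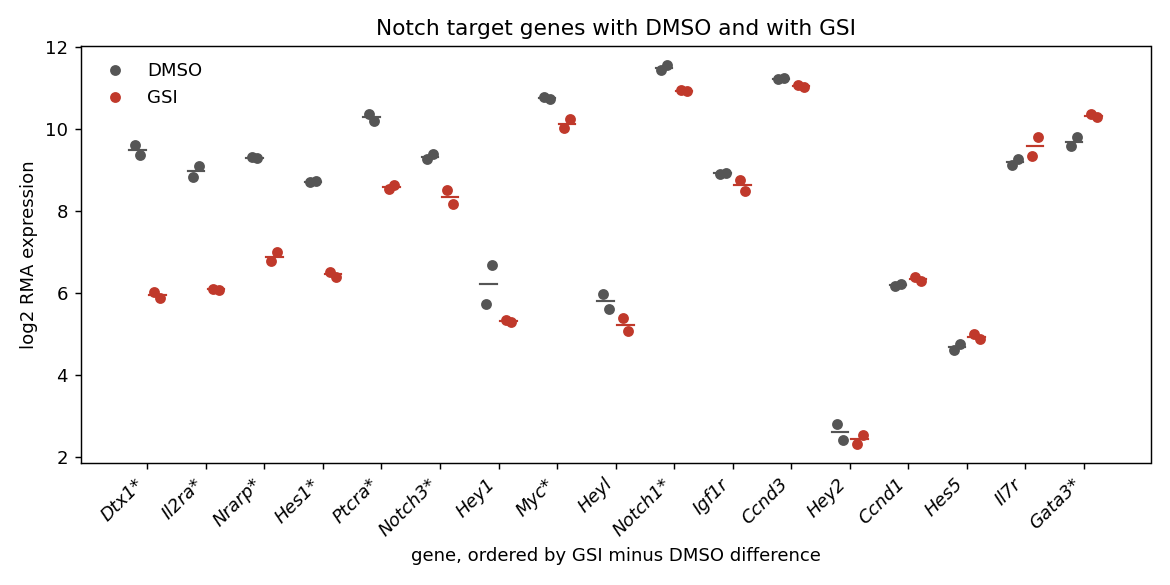
Log2 expression of the 17 measured Notch target genes (points: single arrays, 2 per group; lines: group means; asterisk: adjusted p under 0.05). Dtx1 lies at 9.49 with DMSO and 5.96 with GSI, and Gata3 at 9.69 and 10.33.

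Of 29 components of the Notch pathway, 4 fell and 25 did not pass, against 4 lower and 1 higher when adjusted over the list alone. The falls were the receptor genes Notch1, Notch3 and Notch4 (-0.69 on the log2 scale) and Mfng (-0.58), encoding a glycosyltransferase that modifies Notch. The list as a whole did not pass (camera, adjusted p = 0.381), and Notch4 did not pass as the mean of its probe sets (-0.26, adjusted p = 0.161).

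All 37 measured ribosome biogenesis genes had lower means with GSI, with a median of -0.54 on the log2 scale, and 13 passed, 35 when adjusted over the list alone. The list passed camera (adjusted p = 2.07e-19), not with an estimated correlation (adjusted p = 0.466) or by directional fry (adjusted p = 0.0792). Polr1b, a subunit of RNA polymerase I, fell 1.79-fold, and the nucleolar genes Nolc1, Rrp12 and Bop1 fell 1.67-fold, 1.63-fold and 1.59-fold. Of 23 genes of nucleotide, one-carbon and polyamine synthesis 22 had lower means, 5 fell past the threshold, and 15 when adjusted over the list alone. This list too passed camera (adjusted p = 1.23e-09), not with an estimated correlation (adjusted p = 0.466) or by directional fry (adjusted p = 0.0770). Srm, encoding spermidine synthase, fell 1.92-fold, Cad, which starts pyrimidine synthesis, 1.63-fold, the folate enzyme gene Mthfd1 1.53-fold and the purine synthesis gene Gart 1.51-fold. Of these genes Polr1b, Nolc1, Rrp12, Mthfd1 and Gart did not pass when every probe set was tested, and Bop1 and Gart did not as the mean of their probe sets.

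Glycolysis genes had a median difference of -0.64, but 0 of 13 passed limma and 3 were lower at an unadjusted p under 0.05. Hexokinase Hk2 differed by -1.07 (adjusted p = 0.178) and Pgam1 by -0.83 (adjusted p = 0.219). The list passed camera (adjusted p = 0.0368), not with an estimated correlation (adjusted p = 0.656). The DMSO arrays differed from each other in the same genes, all 13 being higher on DMSO replicate 2 than on DMSO replicate 1, by a median of 0.95, and so did the GSI arrays, with all 13 higher on GSI replicate 2, by a median of 0.39. Without DMSO replicate 2 the list's median was -0.14 and its camera test pointed up, and without GSI replicate 1 the median was -0.34. Without DMSO replicate 1 the median was -1.06. With 1 array left out, the arrays numbered 1 and 2 were no longer balanced between groups. These medians therefore also carry the difference between the numbers. With the replicate number as a block the list still passed camera with the preset correlation.

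No single gene of the G1/S or G2/M lists passed the main test, and some did under other settings. Of 38 genes of G1/S and DNA replication 0 passed limma, with 1 higher and 6 lower at an unadjusted p under 0.05. E2f2 differed by 0.43 (adjusted p = 0.0520) and Gins2 by -0.34 (adjusted p = 0.106). The list's median of -0.11 passed camera (adjusted p = 0.00955), but not with an estimated correlation (adjusted p = 0.656) or without GSI replicate 1 (median -0.041, adjusted p = 0.505). Without GSI replicate 2 the median was -0.18. Of 33 genes of G2/M and mitosis 0 passed limma, with 1 higher and 1 lower at an unadjusted p under 0.05 and a list adjusted p of 0.687. Ccnb2 differed by 0.27 and Plk1 by -0.25. E2f2 passed with centred arrays, cyclic loess, probe set means, dim genes left out and the trend and robust prior (adjusted p = 0.0115 to 0.0477). Gins2 passed with dim genes left out (adjusted p = 0.0482) and with the trend and robust prior (adjusted p = 0.0325), and Ccnb2 with the latter (adjusted p = 0.0227).

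Of 12 genes of cyclin-dependent kinase inhibitors and G1 cyclins, 1 rose, Cdkn1a, the inhibitor p21 (2.26-fold), and 2 when adjusted over the list alone. Of 22 p53 targets 3 rose: Trp53inp1 (2.60-fold), the antiproliferative gene Btg2 (2.31-fold) and Cdkn1a. Adjusted over the list alone, 9 p53 targets were higher and 2 lower. Of 19 apoptosis regulators 2 rose, the proapoptotic gene Bmf (2.33-fold) and the inhibitor of apoptosis Birc3 (1.46-fold), and 5 were higher and 2 lower adjusted over the list alone. Of 16 FoxO targets 1 rose, Pik3ip1, encoding a negative regulator of phosphoinositide 3-kinase (1.72-fold), and 6 adjusted over the list alone. These lists passed camera (adjusted p = 0.0308, 0.00821, 0.0428 and 0.00198), and none of the 4 did with an estimated correlation (adjusted p = 0.520, 0.466, 0.466 and 0.510). Without DMSO replicate 1 the kinase inhibitor, p53 and apoptosis lists did not pass (adjusted p = 0.0838, 0.0503 and 0.0503). Without GSI replicate 1 the kinase inhibitor and apoptosis lists did not (adjusted p = 0.0716 and 0.132), nor did the apoptosis list without DMSO replicate 2 (adjusted p = 0.0847).

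Genes of T cell development moved in both directions. Among 17 thymocyte stage markers 5 rose, Ccr9, Cd8a (2.11-fold), Cd8b1 (1.96-fold), the stem cell factor receptor gene Kit (1.81-fold) and Cd4 (1.68-fold), and 2 fell, Il2ra and Ptcra. Among 18 genes of the T cell receptor complex and its proximal signalling 5 rose, led by the costimulatory receptor gene Cd28 (2.30-fold), the receptor zeta chain gene Cd247 (1.75-fold), Themis (1.62-fold) and the kinase gene Prkcq (1.53-fold). One receptor chain gene, Cd3g, fell by 0.47 on the log2 scale. Cd8b1, Kit, Cd4 and Cd3g were named after their values were seen. Among 28 T-lineage transcription factors Tox (1.77-fold), Gata3 and Gfi1 (1.52-fold) rose and Lef1 fell 1.58-fold. Adjusted over the list alone, 6, 9 and 10 members of these lists were higher and 3, 4 and 2 lower. All 3 lists passed camera upwards (adjusted p = 0.0137, 0.0194 and 0.00741), and none did with an estimated correlation (adjusted p = 0.466, 0.520 and 0.466). Without DMSO replicate 1 the thymocyte list had an adjusted p of 0.0503, and without GSI replicate 1 the receptor list had 0.0738.

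Of 24 measured genes of lysosome and autophagy, 9 rose, 16 when adjusted over the list alone, with a median of 0.40 on the log2 scale. The list passed camera (adjusted p = 3.12e-10), not with an estimated correlation (adjusted p = 0.466) or by directional fry (adjusted p = 0.0509). The cathepsin genes Ctsl and Ctsd rose 2.75-fold and 1.83-fold, the progranulin gene Grn 2.02-fold and Wipi1, which acts in autophagosome formation, 1.81-fold. Of 20 cholesterol synthesis genes 19 had higher means and 2 passed, 5 when adjusted over the list alone. The list passed camera (adjusted p = 3.13e-06), not with an estimated correlation (adjusted p = 0.520). The genes that passed were Insig1 (1.51-fold), which restrains sterol synthesis, and the sterol reductase gene Tm7sf2 (1.51-fold). Insig1 and Tm7sf2 did not pass when every probe set was tested (adjusted p = 0.0515 and 0.0855).

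Stress and interferon lists did not pass camera. In the integrated stress and unfolded protein response 1 of 18 rose, the cystine transporter gene Slc7a11 (2.15-fold), and 1 fell, Cth (1.65-fold; list adjusted p = 0.295). Of 10 heat shock protein genes 1 fell, the mitochondrial chaperonin gene Hspd1 (1.43-fold; list adjusted p = 0.152). Of 17 interferon-stimulated genes 2 rose, Bst2 (1.89-fold) and Mx1 (1.69-fold; list adjusted p = 0.163). Adjusted over the list alone, 3, 1 and 3 genes were higher and 6, 2 and 1 lower.

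Markers of other cell types stayed mostly dim, with median log2 levels of 4.38 to 4.46 per list, and none of these 5 lists passed camera. Of 8 natural killer and cytotoxic markers Gzma, encoding granzyme A, rose 2.28-fold from a high level of 11.72 (list adjusted p = 0.201). Of 10 stromal and epithelial markers Pdgfrb, a growth factor receptor gene, fell 2.43-fold (list adjusted p = 0.410), and of 11 B cell markers the adaptor gene Blnk rose 1.40-fold (list adjusted p = 0.445). Of 14 myeloid markers 0 passed limma and 1 was higher at an unadjusted p under 0.05, Itgam, which differed by 1.05 (adjusted p = 0.0561) and passed with centred arrays, cyclic loess, probe set means and the trend and robust prior (adjusted p = 0.0132 to 0.0378). Cd14 differed by -0.22. The myeloid list's median was -0.011 while its mean was 0.069 and its test pointed up (adjusted p = 0.589). Of 6 erythroid markers 0 passed limma and 1 was higher at an unadjusted p under 0.05 (list adjusted p = 0.540). Gata1 differed by 0.28 and Epor by -0.20. Adjusted over the list alone, 1 marker each of the killer, B cell and myeloid lists and 1 stromal marker were higher, and 1 stromal marker was lower.

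**Figure D3:**
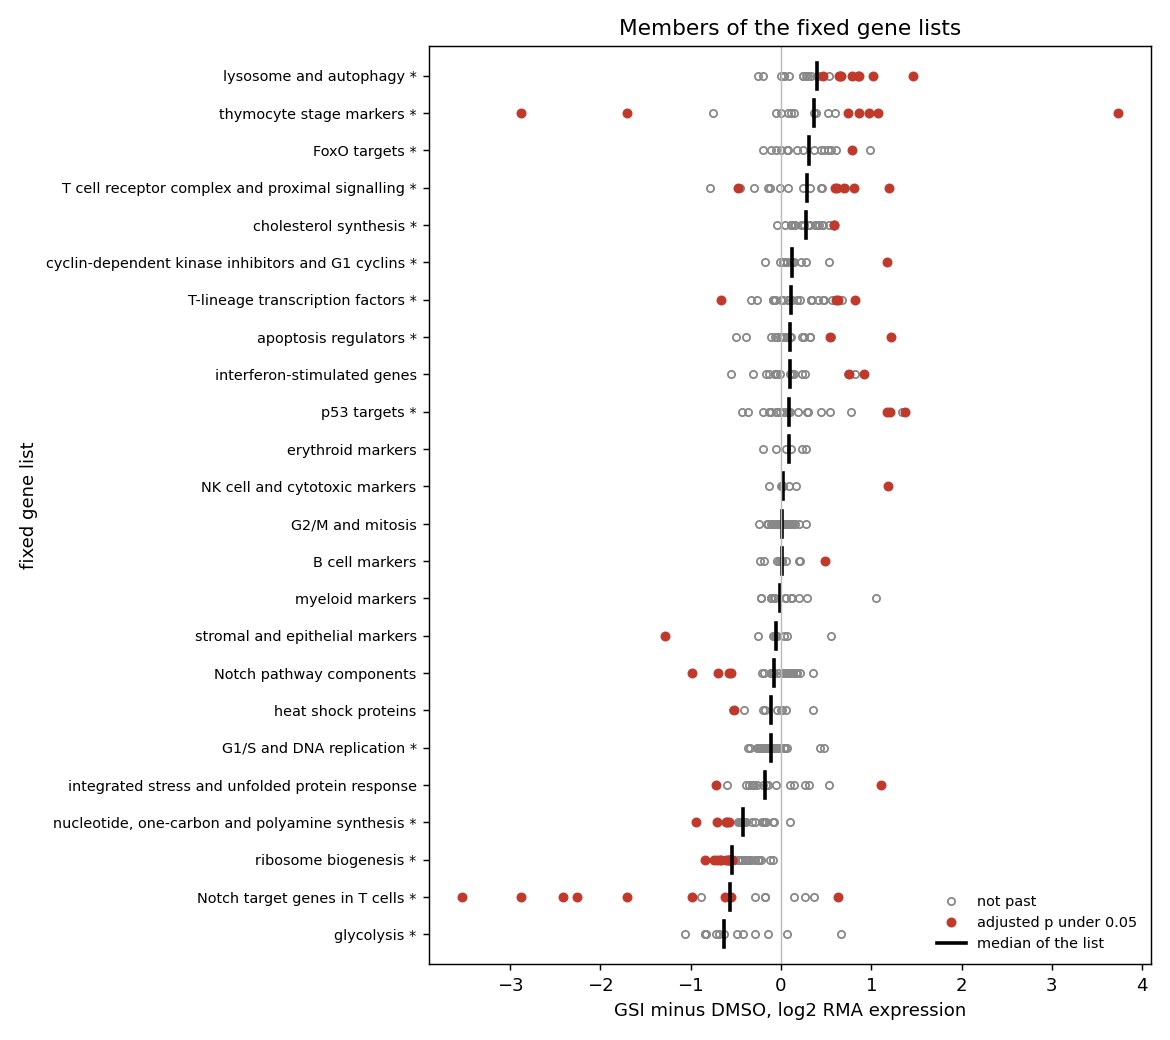
Difference between GSI and DMSO in log2 expression for every measured member of the 24 gene lists (filled points: adjusted p under 0.05; bars: list medians; asterisk: adjusted p under 0.05 by camera with the preset correlation). The ribosome biogenesis list has its median at -0.54 and the lysosome and autophagy list at 0.40.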

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

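The probe sets that the platform annotation used here does not pair with 1 gene were left out of the gene-level tests and gene lists of the report. Tested with all other probe sets against the DMSO arrays, 46 of these 10092 probe sets were higher with GSI and 24 lower (limma, adjusted p under 0.05). The largest differences were 1.93 and 1.59 upwards, and -3.90 and -2.25 downwards, on the log2 scale. Their genes were not analysed here.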

How the results depend on the processing

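With 2 arrays per group, the counts of changed genes depended on the settings. The main counts were 466 up and 284 down. They were 898 and 685 with dim genes left out, which tests fewer genes, 1042 and 899 with an intensity trend and robust prior, and 111 and 66 with a 2-fold minimum. Leaving out 1 array gave 0 to 1 up and 0 to 5 down, the lone array being assumed to vary like the other group. The counts stayed within 1.5 times for every probe set on its own, the mean of a gene's probe sets, centred arrays and cyclic loess. With the replicate block they were 147 up and 70 down, 204 of these 217 being among the 750. The labels do not say that equal numbers pair the samples, and the deviations of DMSO replicate 1 and GSI replicate 1 from their group means correlated at 0.085 across genes. A block with the numbers crossed between groups called fewer, 1 gene up and 13 down. Hypoxia and glycolysis genes were higher on the arrays numbered 2 in both groups. These values lean towards pairing by number without showing it, so pairing stays open. The main fit took no pairing into account. Of 73 named genes called, all kept their direction wherever they were tested. Only probe set means, centring and loess could have turned a direction. The other settings kept the same differences, or left out 1 array from groups that did not overlap. Still called were 53 when every probe set was tested, 68 with probe set means, 72 of 72 without dim genes, 72 with the trend, 73 with centring or loess, 40 with the block and 42 with the 2-fold minimum. Without DMSO replicate 1 or DMSO replicate 2 it was 6, and without GSI replicate 1 or GSI replicate 2 it was 0 (limma, 2356 and 3093 genes at an unadjusted p under 0.05).

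With an estimated correlation every one of the 14 list calls was lost. The adjusted p was 0.466 for Notch targets, ribosome biogenesis, nucleotide synthesis, p53 targets, apoptosis, thymocyte stage, T-lineage factors and lysosome, 0.510 for FoxO targets, 0.520 for cholesterol, kinase inhibitors and T cell receptor, and 0.656 for glycolysis and G1/S. That form of camera rests on the 2 residual degrees of freedom, so a list could hardly pass it after adjustment. For Notch targets the estimated correlation was only 0.0085, under the preset 0.01, and the unadjusted camera p was still 0.0352. Over the 14 called lists the estimate ran from -0.0078 for p53 targets to 0.955 for glycolysis. It was 0.524 for ribosome biogenesis and 0.732 for cholesterol, but 0.0106 for apoptosis and 0.0174 for T-lineage factors. Where the estimate lies above the preset 0.01, the camera p-value with the preset may be too small. By ranks the apoptosis and receptor lists had 0.0672 and 0.104. Without dim genes the apoptosis, kinase inhibitor and glycolysis lists had 0.0899, 0.0969 and 0.0698. The apoptosis list had 0.0544 with cyclic loess and 0.108 with probe set means; the cause was not tested. Leaving out each array in turn, adjusted p ranged from 0.0369 to 0.132 for apoptosis, 0.027 to 0.0838 for kinase inhibitors, 0.0041 to 0.0503 for p53 targets, 0.0134 to 0.0503 for thymocyte stage, 0.0164 to 0.0738 for the receptor, 1.64e-05 to 0.505 for G1/S and 4.51e-07 to 0.778 for glycolysis, where the test turned upwards without DMSO replicate 2. The medians of called lists that moved over 1.5 times when an array was left out were those of apoptosis (0.10 in the main test, 0.044 to 0.17), cholesterol (0.28, 0.15 to 0.43), G1/S (-0.11, -0.041 to -0.18), glycolysis (-0.64, -0.14 to -1.06), p53 targets (0.088, up to 0.18) and thymocyte stage (0.37, down to 0.12). All other list calls kept their side under these alternatives. Arrays of 2 per group and dim probe sets near background limit what small changes can be seen.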

Other observations

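The genes given here, all but Il2ra outside the fixed lists, were chosen after their values were seen, and no gene family was tallied or tested. Gbp6 rose by 1.35, Gbp8 by 1.33, Ifi47 by 0.99, Gbp2b by 0.97 and Igtp by 0.64 on the log2 scale (limma, adjusted p = 0.00478 to 0.0463). These encode GTPases, their probe sets can bind related copies, and the fixed interferon list did not pass. Of single cytokine receptor genes, Il10rb rose by 1.54, Il21r by 1.28, Ifngr1 by 0.85, Ifnar2 by 0.60 and Ifnar1 by 0.59, while Il15ra fell by 1.45 and Il2ra by 2.87. Mxd4, encoding a transcriptional antagonist of Myc, rose by 1.45, while Id1, encoding an inhibitor of helix-loop-helix factors, fell by 2.01 and Deptor, encoding an inhibitor of mTOR, by 1.35. The costimulatory receptor gene Cd27 rose by 1.31. In limma 0 genes, these included, were called without GSI replicate 1 or without GSI replicate 2, with 2356 and 3093 genes at an unadjusted p under 0.05.

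Of the tests below, the RNA degradation test and the test without each DMSO array were chosen after values bearing on them had been seen. The clusters, the difference between replicates and the ribosome list were noticed in these data, and what is said of them is a hypothesis.

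Genes called in the same direction lay next to each other more often than chance. In the gene order of GRCm38.p6, 64 neighbouring pairs were called in the same direction, 44 up and 20 down, against a mean of 18.1 and a highest value of 35 in 10000 draws matched on mean expression (one-sided permutation p = 1e-04, the smallest these draws can give), which argues against clustering of expressed genes as the whole cause. Examples are Slc6a20a, Lztfl1 and Ccr9, then Rbm17, Il2ra and Il15ra, then Ddx54, Rasal1 and Dtx1, and Myc with Pvt1. Paralogs were recognised by the shared first 3 letters of their symbols, which misses relatives such as Ifi204 and Mndal. Leaving out pairs sharing these letters left 55 pairs against a highest of 33, which argues against probe sets shared between like-named paralogs. With such pairs again left out, pairs 2 places apart around an uncalled gene numbered 25 against a mean of 16.4 (one-sided permutation p = 0.0282, short of the bound of 0.025), so overlapping or read-through transcripts cannot be told apart from a regional effect of the inhibitor, which may act through shared regulatory elements but was not tested.

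Genes of the hypoxia response were higher on the array numbered 2 in both groups. Bnip3 stood at 7.03 and 10.34 on the DMSO arrays and at 7.84 and 9.09 on the GSI arrays. Over 19 further hypoxia genes whose values had not been looked at, replicate 2 exceeded replicate 1 by a median of 0.41 with DMSO (17 of 19 higher) and 0.20 with GSI (14 of 19 higher), above all 10000 matched lists in each, so a difference in oxygen supply or density between cultures, if the replicates were separate ones, is a candidate explanation. After cyclic loess the median difference was 0.42 with DMSO and 0.19 with GSI (13 of 19 higher), against array scaling that loess can remove. The values were already normalized between arrays, so loess could move them little. The Gapdh and Actb controls differed in 3' minus 5' signal by at most 0.050 between the DMSO arrays, under the bound of 0.3. At these controls that argues against RNA degradation. The transferrin receptor control differed by 0.35 between the DMSO arrays, above that bound, and by -0.30 between the GSI arrays. Its direction did not follow the pattern in both groups, but it leaves degradation between the DMSO arrays open.

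The ribosome biogenesis list, whose camera call was lost with an estimated correlation (adjusted p = 0.466), had a median log2 difference of -0.54, below the lowest median of 10000 random lists matched on mean expression (-0.18), which argues against an intensity-dependent bias. Without DMSO replicate 1 the median was -0.43 and without DMSO replicate 2 it was -0.57, so a difference between the 2 DMSO arrays does not account for all of it. A lower output of this gene group with GSI, which may go with the lower Myc level, remains a hypothesis, since no test here separates it from other effects of the inhibitor.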
